A study of Mus musculus with 6 samples.

How the data were processed

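Total RNA was extracted with Trizol, per the labels' protocols, and biotinylated cRNA was made from 8 ug of it and hybridised to 1 Affymetrix mouse array per sample. The labels give 3 control GFP shRNA samples and 3 PRDM2 shRNA samples, all C2C12 cells after 28 hours in 2% horse serum, numbered 1 to 3 in each group and called biological replicates. Samples were grouped by their titles, and each column of the value table was matched to its sample.

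The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes, the authors used GCOS and PLIER, with no version, role or order given, and the normalization between arrays is not given in the sources used here. The table holds 45101 probe sets for each of 6 arrays, and 0 further columns of samples. Of these, 64 control probe sets were left out, and the spike-in, Actb and Gapdh probe sets among them were used only to compare arrays. In the column of control replicate 2, 4 probe sets of Gngt1 held the number 14699, which is that gene's Entrez number, while the same probe sets read at most 5.18 in the other arrays. These 4 probe sets were left out, which leaves 45033. Gene names came from the platform annotation, with 34941 probe sets naming 1 gene, 932 naming several and 9160 unnamed here. By Entrez number, 34737 probe sets matched a gene table of assembly GRCm38.p6, which changed 0 symbols. No genome coordinates are printed, since the sources used here give no build for the files.

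Values were taken as log2(intensity + 16), so a fold change understates the change of dim genes. A rule set before the data were examined kept the deposited scaling if the quartiles of the 6 columns differed by under 0.1, and otherwise called for quantile normalization. The ranges were 0.02 for the lower quartile, 0.04 for the median and 0.15 for the upper quartile, so quantile normalization was used. A gene was represented by the probe set naming it alone with the highest mean over the 6 arrays, giving 18192 genes, with no filter on dim genes. Between 42.5% and 43.4% of probe sets read above 16 units per array. The number of arrays, 3 per group, limits the precision.

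Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values are over all genes, except where a count is adjusted over a gene list alone. The 28 gene lists, with 1053 entries of which 973 were measured, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation, on ranks, and with fry, adjusted over the 28 lists. Standard errors are limma's moderated ones.

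Named genes were fixed by rule before the data were examined. The rule always names 11 genes, including Prdm2, Myod1 and Myog. It adds the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups do not overlap and whose higher group mean is at or above the median gene. It further adds, per list, the 3 members past the threshold with the largest change or, in a called list without any, the 2 members of smallest p. Clone and predicted-locus names were skipped. With no gene past the threshold in all 6 arrays, the rule was also applied to the fit without control replicate 2, a use decided after the data were seen. For named genes, probe sets of the same gene pointing the other way were counted in that fit.

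The replicate numbers were checked for pairing. Deviations from the group means correlated between same-numbered arrays at 0.34, 0.59 and 0.66 over 18192 genes. For 6 of 6 arrays the best partner in the other group had the same number. All 3 correlations exceed the 0.1 set for calling the numbers paired, so the fit with the replicate number as a block was read as a paired one. The pairing was taken from the data and not from a statement in the labels. In log2 values, control replicate 1 correlated at 0.9759 with knockdown replicate 1 and at 0.9773 with knockdown replicate 3. Control replicate 2 correlated at 0.9977 with knockdown replicate 2, which may reflect like RNA and not joint processing. The correlations therefore do not establish the pairing for numbers 1 and 2. Ratios of 3' to 5' control probe sets were alike by number (control and knockdown in turn). For Gapdh they were 0.977 and 0.974 for number 1, 0.940 and 0.933 for number 2, and 1.097 and 1.087 for number 3. For Actb they were 1.62 and 1.60, 1.39 and 1.45, and 1.77 and 1.71. This goes with joint processing, but like RNA could also give it for number 2. The dap spike-in did not tell numbers 1 and 2 apart.

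Alternatives were the deposited scaling, median centring, offsets of 1 and 64, leaving out the dimmest genes, the mean of a gene's probe sets, all probe sets separately, eBayes with trend and robust settings, array weights, the replicate block, leaving out each array in turn, treat at a log2 fold change of 0.5, and the other list tests. The steps were tested on simulated arrays with the means of the 18192 genes, in which 200 genes at or above the median level were changed. Noise was drawn independently for each gene and array, without pairing or a misplaced array. The counts therefore test the steps and do not say how many changes the real arrays could show. With 3 arrays against 3 and the spread of all 6 arrays, 84 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were called, with 14 false calls. With 2 control and 3 knockdown arrays and their own spread, 94 of 100 and 100 of 100 were called, with 12 false calls.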

Results

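Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with RNA from C2C12 cells, a mouse myoblast line that leaves the cell cycle and forms contractile myotubes when serum is lowered. All cells had spent 28 hours in medium with 2% horse serum. The labels put 3 arrays in a control group, whose cells carried a short hairpin RNA (shRNA) against GFP, and 3 in a group whose cells carried an shRNA against PRDM2, a PR domain protein that methylates histone H3 at lysine 9. The labels call the 3 arrays of each group biological replicates. The arrays' median intensities lay between 10.7 and 11.4 units, and the number of arrays limits the precision. The comparison asks how expression during differentiation differs when PRDM2 is targeted.

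Prdm2 messenger RNA, the target, was not lower on the arrays labelled PRDM2 knockdown. Its brightest probe set read 6.19, 6.42 and 5.94 log2 units in control replicates 1, 2 and 3, and 6.67, 6.32 and 6.02 in knockdown replicates 1, 2 and 3. The log2 fold change was 0.15 (SE 0.19, 95% interval -0.31 to 0.62, n = 3 per group, adjusted p = 1.00 with limma). The other 2 probe sets of Prdm2 gave 0.07 (SE 0.18) and 0.12 (SE 0.09). The probe set at 0.12 read between 11.8 and 17.5 units on every array, around the offset of 16, so its small SE is no sign of precision. Where these probe sets lie relative to the sequence targeted by the shRNA was not analysed here. The target's mRNA therefore does not separate the 2 groups, and every direction below rests on the labels alone.

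With all 6 arrays, no single gene passed the threshold, and gene lists fixed beforehand were called only where a small correlation between genes was preset. Of 18192 genes, 0 were higher and 0 lower on the knockdown arrays at an adjusted p of 0.05 (limma). At an unadjusted p under 0.05 there were 600 genes, against 909.6 expected by chance. With the replicate number as a block there were again 0 calls, with 1641 genes at an unadjusted p under 0.05. Of the 28 lists, 7 were shifted upwards and 2 downwards by camera with a preset correlation between genes. With an estimated correlation 0 of the 28 lists were called, and the smallest adjusted p was 0.43. The estimate was 0.75 for DNA replication and 0.21 for sarcomere and contraction, far above the preset 0.01. Where genes move together in this way, camera's p-values at the preset correlation are too small. For smooth muscle and myofibroblast markers the estimate was 0.0054, and that list lost its call too.

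Cholesterol and fatty acid synthesis had the smallest p of the 28 lists. Of its 29 measured members 22 were on the higher side, with a median log2 fold change of 0.15 (camera adjusted p = 1.3e-04; adjusted p = 0.44 with an estimated correlation). Dhcr7, which catalyses the last step of cholesterol synthesis, had a log2 fold change of 0.37 (SE 0.11), and Fasn, the fatty acid synthase, 0.19 (SE 0.08). Smooth muscle and myofibroblast markers had a median of 0.19, with 13 of 20 members on the higher side (adjusted p = 8.3e-04; adjusted p = 0.43 with an estimated correlation). Its members Actg2 and Tagln, an actin and an actin-binding protein of smooth muscle, stood at 1.30 (SE 0.43) and 1.28 (SE 0.43). Myoblast fusion genes had a median of 0.09, with 18 of 28 on the higher side (adjusted p = 0.0039; adjusted p = 0.44 with an estimated correlation). Among them were Adam12, at 0.84 (SE 0.23), and Jam3, at 0.50 (SE 0.15), with 1 of the 2 probe sets of Jam3 pointing the other way without control replicate 2. These 3 lists were called whichever of the 6 arrays was left out, but the size of the shifts varied. Medians ranged from 0.09 (without knockdown replicate 1) to 0.20 for cholesterol and fatty acid synthesis, from 0.13 (without control replicate 1) to 0.21 for smooth muscle markers and from 0.04 (without control replicate 3) to 0.13 for myoblast fusion.

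Sarcomere and contraction genes, which build the contractile apparatus of muscle, had a median of 0.12, with 41 of 59 members on the higher side (adjusted p = 0.0072; adjusted p = 0.72 with an estimated correlation). Members Tcap and Ckb stood at 0.62 (SE 0.21) and 0.42 (SE 0.14). This shift rested on control replicate 1, without which the median was -0.0032 (adjusted p = 0.99), and without knockdown replicate 3 the adjusted p was 0.053. Mean values of the list were 8.09 in control replicate 1 and between 8.47 and 8.55 in the other arrays. Inflammatory and NF-kB targets had a median of 0.10 in 32 members (adjusted p = 0.0072; adjusted p = 0.44 with an estimated correlation). They included Ptgs2, a prostaglandin synthase, at 1.62 (SE 0.57), and Rela, a subunit of NF-kB itself, against the list's direction at -0.42 (SE 0.14). Without control replicate 1 or 3 this call was lost, at medians of 0.07 and 0.08 (adjusted p = 0.090 and 0.066).

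Extracellular matrix and collagen genes had a median of 0.09 in 57 members (adjusted p = 0.010; adjusted p = 0.52 with an estimated correlation). Their basement membrane collagen Col4a1 stood at 0.72 (SE 0.24), and Dcn, which encodes the collagen-binding proteoglycan decorin, against the list's direction at -1.89 (SE 0.67). This call was lost without control replicate 1 (median 0.07, adjusted p = 0.069), without control replicate 3 (median 0.06, adjusted p = 0.17), without knockdown replicate 1 (median 0.12, adjusted p = 0.073) and without knockdown replicate 2 (median 0.11, adjusted p = 0.28). Wnt signalling genes had a median of 0.05 in 47 members (adjusted p = 0.039; adjusted p = 0.44 with an estimated correlation). Wnt9a stood at 0.67 (SE 0.24), and Nkd1, an inhibitor of the pathway, at 0.38 (SE 0.08), although 2 of the 4 probe sets of Nkd1 pointed the other way without control replicate 2. The Wnt call was lost without control replicate 2 (median 0.02, adjusted p = 0.057), without control replicate 3 (median 0.03, adjusted p = 0.066), without knockdown replicate 1 (median 0.04, adjusted p = 0.24) and without knockdown replicate 3 (median 0.04, adjusted p = 0.053).

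DNA replication genes were shifted downwards, with 44 of 49 members on the lower side and a median of -0.17 (camera adjusted p = 1.9e-04; adjusted p = 0.72 with an estimated correlation). Rfc5, a subunit of the clamp loader, stood at -0.27 (SE 0.11). Tk1, the thymidine kinase that is abundant in S phase, stood against the list's direction at 0.43 (SE 0.17). The call was lost without control replicate 1 (median -0.02, adjusted p = 0.53) and without knockdown replicate 2 (median -0.06, adjusted p = 0.51). List means were 7.33, 6.71 and 7.13 in control replicates 1, 2 and 3, and 7.03, 6.70 and 6.99 in knockdown replicates 1, 2 and 3. Oxidative phosphorylation genes had a median of -0.09, with 37 of 49 on the lower side (adjusted p = 0.0039; adjusted p = 0.52 with an estimated correlation). Cox7a1, a subunit of cytochrome c oxidase, stood at -0.47 (SE 0.16), and Idh3a, an enzyme of the citric acid cycle, at 0.34 (SE 0.14). This call was lost without control replicate 3 (median -0.04, adjusted p = 0.17) and without knockdown replicate 2 (median -0.06, adjusted p = 0.12).

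**Figure D1:**
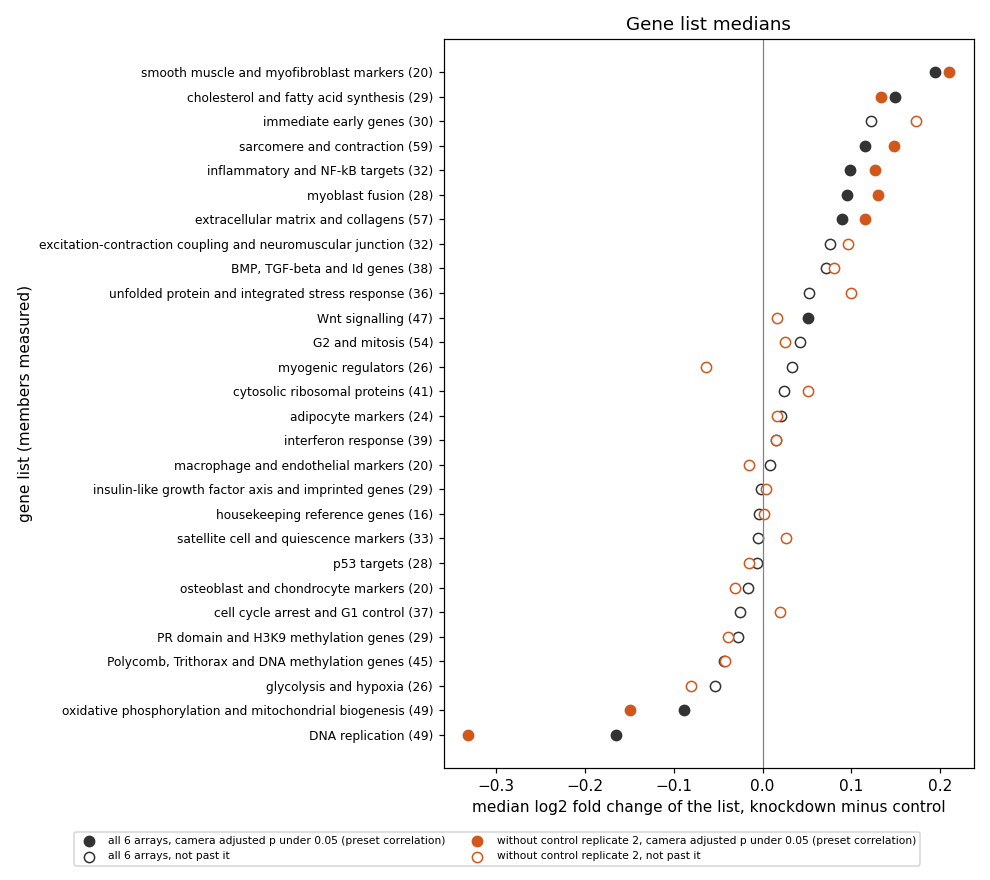
Median log2 fold change (knockdown minus control, x axis) of the measured members of each of the 28 gene lists (y axis, number measured in parentheses), for all 6 arrays in black and without control replicate 2 in orange; filled points passed camera's adjusted p of 0.05 with a preset correlation. DNA replication lies lowest, at -0.17 and -0.33, and no list passed with an estimated correlation in either fit.

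Myogenic regulators as a list were not called (median 0.03 over 26 members, adjusted p = 0.83), nor were G2 and mitosis genes (median 0.04 over 54 members, adjusted p = 0.26). Myod1 and Myog, the transcription factors that commit and differentiate myoblasts, had log2 fold changes of 0.03 (SE 0.13) and 0.10 (SE 0.14). The sign of Myod1 turned in several alternatives, to -0.08 without control replicate 2. Cell cycle genes fixed beforehand did not pass either, with 0.06 (SE 0.08) for the cyclin Ccna2, -0.41 (SE 0.20) for the cyclin Ccnd1 and 0.30 (SE 0.16) for the proliferation marker Mki67. The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn1c stood at 0.19 (SE 0.11) and 0.34 (SE 0.36), and Cdkn1c turned to -0.10 without control replicate 1. Pax7, a satellite cell factor, lay near the floor of the scale at -0.15 (SE 0.10), and Ccnb1 was not measured by a probe set of its own.

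The array labelled control replicate 2 lay apart from the other control arrays. Over the 4548 genes that make up the 25% with the highest means, the median absolute deviation (MAD) of its log2 difference was 0.37 from control replicate 1 and 0.35 from control replicate 3, but 0.07 from knockdown replicate 2. That was the smallest distance among the 15 pairs of arrays, the next being 0.19. Nefl, a neurofilament gene, shows the pattern, with log2 values of 9.17 and 8.50 in control replicates 1 and 3, 4.18 in control replicate 2, and 4.13, 4.06 and 4.16 in the knockdown arrays. Each count was therefore also made without control replicate 2.

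**Figure D2:**
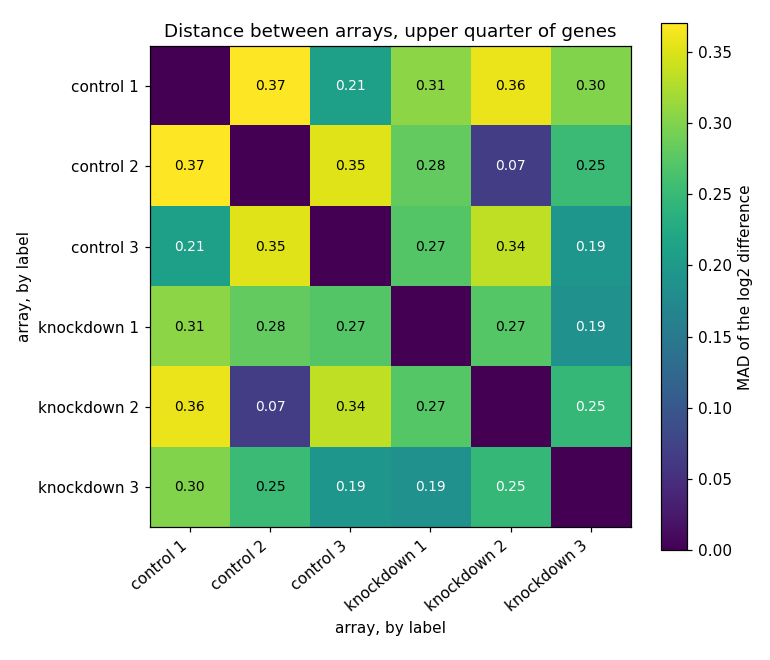
Distance between each pair of the 6 arrays (both axes, by label), as the MAD of the log2 difference over the 4548 genes that make up the 25% with the highest means; colour and printed number give the distance in log2 units. Control 2 and knockdown 2 differ by 0.07, while control 2 differs from control 1 and control 3 by 0.37 and 0.35.

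Without control replicate 2, 291 genes passed at an adjusted p of 0.05, 163 higher and 128 lower on the knockdown arrays, and 84 and 63 of them by at least 2-fold. Planned in advance as 1 of 6 fits that each leave out an array, it was the only 1 of the 6 with any call. It was singled out after the data were seen, so its p-values are optimistic. It compares 2 control with 3 knockdown arrays. In all 291 genes called, the array left out lay nearer to the knockdown mean than to the mean of control replicates 1 and 3. With all 6 arrays, 119 of the 291 had an unadjusted p under 0.05 (limma), and all 291 kept their sign. With both arrays numbered 2 left out, 66 genes were higher and 54 lower without a block, and 409 and 307 with the replicate number as a block. These calls included 111 and 291 of the 291 genes in turn. With the deposited scaling and without control replicate 2, the counts were 75 higher and 80 lower. In the gene values below, "without control replicate 2" applies throughout, and a gene that rose or fell did so in that fit and not with all 6 arrays. Of the 48 named genes past the threshold in it, 9 had a group mean under the median probe set (4.76 log2 units), close to the scale's floor of 4. For these 9 (Cd34, Cilp, Fbln5, Igfbp3, Nefl, Rcan2, Rgs5, Slc14a1 and Tmeff2) the offset sets the printed size, which understates the change in intensity and gives no rank.

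Among muscle genes, members of the same family moved in opposite directions. Myh7, the slow myosin heavy chain, rose by 2.58 on the log2 scale (SE 0.21, adjusted p = 0.0077 with limma), whereas Myh1, a fast myosin heavy chain, fell by 2.93 (SE 0.19, adjusted p = 0.0063), with 1 of its 3 probe sets pointing the other way. Of 59 sarcomere and contraction genes 4 rose and 1 fell, or 7 and 1 adjusted over the list alone. The oxygen carrier Mb rose by 1.13 (SE 0.19), with 1 of its 2 probe sets pointing the other way, and Tcap by 0.88 (SE 0.10). Cav3, the muscle caveolin, rose by 2.68 (SE 0.20), and Rapsn, which clusters acetylcholine receptors, by 0.56 (SE 0.09). Pdlim3, a protein of the Z-disc, fell by 2.15 (SE 0.17). The list was shifted upwards (median 0.15, camera adjusted p = 0.0036; adjusted p = 0.70 with an estimated correlation). Control replicate 1 carried this shift, since the list mean of control replicate 3, 8.51, lay above the 8.47 of knockdown replicates 1 and 2.

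Myf5, a determination factor of the myogenic lineage, fell by 1.90 (SE 0.11, adjusted p = 0.0056), and Mef2c, a transcription factor of differentiating muscle, rose by 1.68 (SE 0.22, adjusted p = 0.027). These were the only 2 of 26 myogenic regulators past the threshold, or 5 higher and 2 lower adjusted over the list alone. The list was not called (median -0.06, adjusted p = 0.62). Myod1 stood at -0.08 (SE 0.11) and Myog at 0.23 (SE 0.12), both short of the threshold. Among 33 satellite cell and quiescence markers 2 rose and 3 fell. The surface proteoglycan Sdc3 fell by 1.75 (SE 0.14), the surface protein Cd34 fell by 1.33 (SE 0.13) and Rgs5 fell by 1.32 (SE 0.09), with 1 probe set each of Sdc3 and Rgs5 pointing the other way.

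Of 57 extracellular matrix and collagen genes 8 rose and 2 fell, or 14 and 5 adjusted over the list alone (median 0.11, camera adjusted p = 3.6e-04; adjusted p = 0.44 with an estimated correlation). Col1a1, a chain of type I collagen, rose by 2.80 (SE 0.25, adjusted p = 0.010), Fbln5, a protein of elastic fibres, by 2.13 (SE 0.32) and Col4a1 by 0.98 (SE 0.15). Dcn fell by 2.74 (SE 0.19, adjusted p = 0.0068). For Dcn and Fbln5 1 of 2 probe sets pointed the other way. Of 20 smooth muscle and myofibroblast markers 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (median 0.21, adjusted p = 5.8e-04; adjusted p = 0.24 with an estimated correlation). They were Actg2, by 1.82 (SE 0.17), Tagln, by 1.80 (SE 0.18), and the growth factor receptor Pdgfrb, by 0.85 (SE 0.14). The matrix protein gene Cilp rose by 3.07 (SE 0.28) and the cadherin Cdh11 by 3.00 (SE 0.21).

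**Figure D3:**
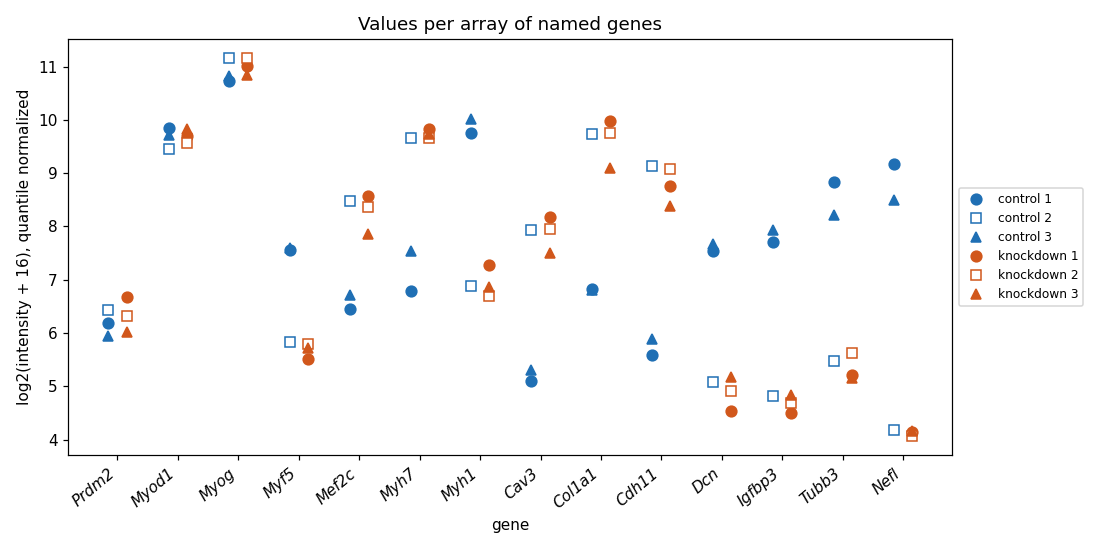
Quantile-normalised log2(intensity + 16) (y axis) of 14 named genes (x axis) in each array, with controls in blue and knockdowns in orange, and open squares for the arrays numbered 2. Control 2 sits with the knockdown arrays for Nefl, at 4.18 against 9.17 and 8.50 in the other controls, while Prdm2 values of the 2 groups overlap.

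Nefl fell by 4.72 (SE 0.19, adjusted p = 0.0015), from a control mean of 8.83 to 4.12, and Tubb3, a tubulin typical of neurons, fell by 3.19 (SE 0.22, adjusted p = 0.0068). Rcan2, a regulator of calcineurin, fell by 2.67 (SE 0.23), the urea transporter Slc14a1 fell by 2.85 (SE 0.12) and the secreted guidance factor Sema3c fell by 2.21 (SE 0.21). Among other genes that rose were Ctrb1, a chymotrypsinogen, by 2.55 (SE 0.21), Rflnb by 2.10 (SE 0.29) and Tmeff2 by 1.88 (SE 0.18), the last with 2 of its 3 probe sets pointing the other way.

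The DNA replication list was lower without control replicate 2, with 47 of 49 members on the lower side and a median of -0.33 (camera adjusted p = 1.45e-11; adjusted p = 0.52 with an estimated correlation). Knockdown replicate 2 had a lower list mean, 6.70, than knockdown replicates 1 and 3, at 7.03 and 6.99. With both arrays numbered 2 left out the median was -0.24, so part of the -0.33 rests on knockdown replicate 2. With only control replicate 2 left out, none of the 49 members passed over all genes, and 0 higher and 4 lower did so adjusted over the list alone. Rfc3 and Rpa2, of the clamp loader and the single-strand binding complex, stood at -0.57 (SE 0.12) and -0.44 (SE 0.09). G2 and mitosis genes had a median of 0.03 (adjusted p = 0.38), with 0 of 54 members past the threshold. Ccnd1 stood at -0.63 (SE 0.12, adjusted p = 0.073), Mki67 at 0.28 (SE 0.19), Ccna2 at 0.08 (SE 0.10), Cdkn1a at 0.28 (SE 0.09) and Cdkn1c at 0.61 (SE 0.34). Cholesterol and fatty acid synthesis had 2 of 29 members past the threshold, Tm7sf2 and Sc5d, enzymes of sterol synthesis, which rose by 1.01 (SE 0.12) and 0.75 (SE 0.11). That list was shifted upwards (median 0.13, adjusted p = 5.8e-04; adjusted p = 0.44 with an estimated correlation). Cox7a1, the 1 member of the oxidative phosphorylation list to pass, fell by 0.65 (SE 0.09), and the list was shifted downwards (median -0.15, adjusted p = 0.0012; adjusted p = 0.47 with an estimated correlation).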

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

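Pairs 1 and 3 alone, the kept Gngt1 probe sets, both settings that pair an estimated correlation with another choice, and the deposited scaling without control replicate 2 were chosen after seeing the data. The other alternatives were planned. The count of genes past the threshold stayed at 0 with all 6 arrays under every scaling, offset, probe set choice and filter, with trend and robust settings, array weights or treat, and with the replicate block. The block gave 7 lists higher and 2 lower, as without it, and changed no call. The signal over background limits dim genes, for which the offset shrinks fold changes. The cause of the changes below was not tested, and neither were fewer arrays or, for an estimated correlation, the wider null it allows.

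Leaving out each array in turn, genes higher ranged from 0 to 163, genes lower from 0 to 128, genes at least 2-fold higher from 0 to 84 and genes at least 2-fold lower from 0 to 63, the upper end each time without control replicate 2 and 0 in the other 5 fits. The Prdm2 log2 fold change ranged from -0.0122 (without knockdown replicate 1) to 0.3128. List medians ranged from -0.0637 (without control replicate 2) to 0.0543 for myogenic regulators, from -0.0032 (without control replicate 1) to 0.2133 for sarcomere and contraction, from -0.3314 (without control replicate 2) to -0.0226 (without control replicate 1) for DNA replication, and from -0.0216 (without knockdown replicate 3) to 0.0705 (without control replicate 3, adjusted p = 0.015) for G2 and mitosis, which was also called without knockdown replicate 1 (adjusted p = 0.042). Lists higher ranged from 4 (without control replicate 1) to 6, and lists lower from 0 (without knockdown replicate 2) to 2. Among other lists, medians ranged from -0.0056 to 0.1628 for excitation-contraction coupling, from -0.032 to 0.0314 for cell cycle arrest, from -0.0108 to 0.0258 for satellite cell markers, from -0.0424 to 0.0138 for the insulin-like growth factor axis, from -0.0306 to 0.0171 for osteoblast markers, from -0.0154 to 0.069 for macrophage and endothelial markers, from -0.0137 to 0.027 for interferon response, from -0.0437 to 0.0994 for unfolded protein response, from -0.0801 to 0.0018 for glycolysis, from -0.0723 to 0.0064 for Polycomb and Trithorax genes, and from -0.0649 to 0.0088 for housekeeping genes. Cdkn1c ranged from -0.1036 to 0.6069 and Myod1 from -0.0798 to 0.1193.

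Signs also turned for values near 0. The insulin-like growth factor list moved to 0.0029 as deposited, 0.0011 with median centring, 0.0318 without the lowest genes and 0.0072 with the mean of probe sets. Myod1 moved to -0.0025 as deposited, -0.0042 with median centring and -0.0287 with the mean of probe sets. Satellite cell markers moved to 0.0064 with offset 64 and 0.0155 without the lowest genes, where macrophage and endothelial markers moved to -0.1547. With array weights, myogenic regulators stood at -0.0262, sarcomere and contraction lost its call at 0.0391 (adjusted p = 0.16), and cell cycle arrest, satellite cell, osteoblast and housekeeping lists moved to 0.0126, 0.0173, 0.01 and 0.0021.

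With an estimated correlation, with fry, and with an estimated correlation under the replicate block, 0 lists were higher and 0 lower, and sarcomere and contraction (median 0.1151) and DNA replication (median -0.1652) lost their calls. The adjusted p for DNA replication was 0.72, 0.77 and 0.50 in turn. With an estimated correlation and without control replicate 2, again 0 and 0 lists were called, with medians of 0.1479 for sarcomere and contraction, -0.3314 for DNA replication, -0.0637 for myogenic regulators, 0.0201 for cell cycle arrest, 0.0258 for satellite cell markers, 0.0044 for the insulin-like growth factor axis, -0.0154 for macrophage and endothelial markers and 0.0012 for housekeeping genes.

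Pairs 1 and 3 alone gave 66 genes higher and 54 lower, 48 and 42 at least 2-fold, and with the replicate block 409 and 307, 123 and 84 at least 2-fold. In both, satellite cell markers stood at 0.0347, macrophage and endothelial markers at -0.012, interferon response at -0.004 and Myod1 at -0.0145. The deposited scaling without control replicate 2 gave 75 higher and 80 lower, 52 and 53 at least 2-fold, with myogenic regulators at -0.0679, cell cycle arrest at 0.0294, satellite cell markers at 0.0255, the insulin-like growth factor axis at 0.0027, macrophage and endothelial markers at -0.0138, housekeeping genes at 0.0012 and Myod1 at -0.1066. Over the named genes and the lists other than the 4 main ones, 1706 values under an alternative kept side and direction. A further 167 gained a call, 45 lost a call and 60 turned in sign. Named genes gained 48 of these calls without control replicate 2 and 28 there with the deposited scaling. In pairs 1 and 3 they gained 31, and 52 with the replicate block. These fits all leave out control replicate 2, and many named genes were chosen for passing without it. No gene passed with every array, so a gene that kept its side stayed uncalled. For genes the counts therefore reflect how they were chosen and do not measure robustness.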

Other observations

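The list tests with all 6 arrays and the fit without control replicate 2 were planned, while the attention to that fit and the tests of array position, hybridisation controls, the Prdm2 interval, the difference between cell cycle lists and the splits were chosen after the results were seen. Without control replicate 2, the insulin-like growth factor binding protein Igfbp3 fell by 3.14 on the log2 scale (SE 0.13, adjusted p = 0.0015 with limma) and Igfbp2 fell by 2.34 (SE 0.24). Igfbp7, a related secreted protein, rose by 1.95 (SE 0.12, adjusted p = 0.0063). Of 29 measured genes of the insulin-like growth factor axis and imprinted genes 1 rose and 4 fell, and the list was not called (adjusted p = 0.54). Among 37 genes of cell cycle arrest and G1 control, the transcription factor Foxo1 rose by 1.04 (SE 0.10), Btg1, an antiproliferative gene, rose by 0.74 (SE 0.12), and Gas2, a growth arrest gene, was 2.83-fold lower (adjusted p = 0.015 with limma).

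In the same fit single members of other signalling lists passed. The ligand Tgfb3 rose by 0.85 (SE 0.12), Wnt10a by 1.09 (SE 0.14) and the transcription factor Tcf7l1 by 0.78 (SE 0.12). Of the inflammatory and NF-kB targets, the cytokine Csf1 rose by 0.80 (SE 0.12) and the adhesion molecule Vcam1 by 0.74 (SE 0.12), while the hyaluronan receptor Cd44 fell by 1.06 (SE 0.15). That list was called by camera (adjusted p = 0.0012; adjusted p = 0.24 with an estimated correlation) and by fry (adjusted p = 0.0047), where it was the 1 list called. In glycolysis and hypoxia, Pfkp fell by 1.08 (SE 0.14) and Egln3 rose by 0.99 (SE 0.16), and the p53 target Zmat3 fell by 0.74 (SE 0.11). With all 6 arrays, smooth muscle and myofibroblast markers were called (median 0.19, adjusted p = 8.3e-04; adjusted p = 0.43 with an estimated correlation). Markers of the other cell types tested were not, with medians of 0.0088 for macrophage and endothelial genes, 0.02 for adipocyte genes and -0.02 for osteoblast and chondrocyte genes. The 19 lists not called with all 6 arrays had medians between -0.05 and 0.12. In 4 of the 28 lists, none of them called, the median, mean and test differed in sign, and without control replicate 2 this was so in 6, none of them called.

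The array labelled control replicate 2 resembled the knockdown arrays. Among 120 genes called from the arrays numbered 1 and 3 alone, its median position between the control mean (0) and the knockdown mean (1) was 0.989, and 117 of the 120 lay past the midpoint. A shared effect on both arrays numbered 2 in these genes would have moved knockdown replicate 2 past the knockdown mean, but its median position was 0.997. Genes whose knockdown values lay at the scale's floor of 4 had no room for such a move. Nefl, at 4.13 and 4.16 in knockdown replicates 1 and 3, was 1 of them, and their number was not counted. The 120 genes were chosen for separating the arrays numbered 1 and 3, so an effect on other genes cannot be seen there. Elsewhere the arrays numbered 2 were alike. DNA replication means were 6.71 in control replicate 2 and 6.70 in knockdown replicate 2, against 7.03 and 6.99 in knockdown replicates 1 and 3. Their maximum intensities, 4685 and 5014.5 units, lay under the 7051.4 or more of the other arrays. A single array deposited under both labels was also argued against. The 18 hybridisation control probe sets, added apart from the sample, read at least 1.353 times as high in knockdown replicate 2, while bright genes had a median ratio of 0.966. RNA of knockdown cells on this array, through a wrong label or tube, may therefore be the source. The MAD of this array from knockdown replicate 2 was 0.068, while knockdown arrays differed from each other by 0.19 to 0.27. That argues against control cells that had only come to resemble the knockdown cells, unless cultures handled together lie closer, which was not tested. Whether RNA of knockdown replicate 2 itself was on both arrays was not tested either.

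Prdm2 mRNA was not lower on the knockdown arrays. A fall of Prdm2 by 1 log2 unit or more, hidden by control replicate 2, was argued against by the fit without that array, in which the log2 fold change was 0.27 with a 95% interval from -0.20 to 0.75, above -1. That PRDM2 was not reduced in these cells stays open. So do an effect on protein alone and probe sets outside the affected transcript, and none of these was tested.

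The DNA replication list was called lower without control replicate 2 and the G2 and mitosis list was not, where fewer dividing cells would lower both. Within pairs 1, 2 and 3 of same-numbered arrays, knockdown minus control was -0.30, -0.011 and -0.13 for the mean of the replication list, and 0.05, -0.0065 and 0.05 for that of the G2 and mitosis list. The replication mean minus the G2 and mitosis mean differed by -0.35, -0.0047 and -0.18 in turn, and pair 2 holds control replicate 2, which may carry RNA of knockdown cells. Without the pairing the groups overlapped once that array was left out (lowest control minus highest knockdown, -0.021). The 2 pairs that remain are too few to decide, so fewer dividing cells stays open, and without control replicate 1 the replication list's median was -0.02.

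The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, so 10 of 10 splits gave as many, and the highest other split called 6. Among the 4 splits that part all 3 pairs of same-numbered arrays the calls were 0 in each, and genes at an unadjusted p under 0.05 numbered 600 in the real split and 501, 66 and 42 in the others. The split that called 6 genes, and 3146 at an unadjusted p under 0.05, set control replicates 1 and 3 with knockdown replicate 3 against the rest. The split of control replicates 1 and 3 with knockdown replicate 1 against the rest had 2636 such genes. Both of these splits part only 1 same-numbered pair and keep control replicate 2 with knockdown replicate 2, while the real split parts all 3 pairs. Their counts therefore cannot be set against that of the real split. Without control replicate 2, the real split of the 5 arrays called 291 genes and was the only 1 of 10 to call as many, the highest other calling 0. That array was singled out because it lay with the knockdown arrays, and leaving it out favours the real split. The comparison therefore cannot speak to chance, and 10 splits are again too few for a share under 0.05.

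The spike-in for the dap transcript, added before labelling, read 41.6 and 44.3 units on the arrays numbered 3 and between 145 and 189 on the others. Among 10092 probe sets unnamed or naming several genes, 0 passed with all 6 arrays, with 271 at an unadjusted p under 0.05, and 13 passed without control replicate 2.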
